A study of Danio rerio with 16 samples.

How the data were processed

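RNA from whole zebrafish larvae was measured by strand-specific total RNA sequencing in 16 libraries, 4 for each of 4 groups: the DMSO solvent control and PCB153 at 0.1, 1 and 10 µM. The deposited files hold, per library, whole-number read counts for 32105 Ensembl genes, with no normalization, and 5 summary lines from the counting program for reads that were assigned to no gene. The submitters' processing notes name Trimmomatic, HTSeq, edgeR and the genome build GRCz10, without versions. The aligner and the annotation release are not given in the sources used here, and no gene coordinates are printed for that reason. The labels name ribosomal RNA removal (Ribo-Zero Gold) in the library preparation. The file names state reverse-strand counting in union mode. The group and replicate number of each library were taken from the labels.

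Gene counts summed to between 8069225 and 15531744 per library. Reads listed as not uniquely aligned made up 26.9% to 57.7% of all entries of a library. Reads that the counting program placed in no counted feature made up 31.4% to 40.4% of the uniquely aligned ones. The latter are called reads outside annotated genes, or outside genes, though they may include reads from introns or from the strand opposite a gene. Neither class can be assigned to a gene from these files. A self-test used simulated counts drawn with the depths and the spread of the real libraries. Chosen genes were changed at 10 µM against DMSO. The test recovered 26 of 50 genes changed 1.3-fold (52%), 36 of 50 changed 1.5-fold (72%) and 46 of 50 changed 2-fold (92%). Of the unchanged genes 12 were called in that comparison. These shares hold for the chosen genes and are not the sensitivity over all genes tested. Variation of whole libraries that moves many genes together could make the real test perform worse.

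Ensembl identifiers were matched to gene symbols through a table of current and older names. A symbol was found for 26269 identifiers, and 4144 of these share their symbol with another identifier, so the identifier is printed where a symbol alone would be ambiguous. Many symbols are in the form of the human gene, and which of a pair of zebrafish duplicates such a gene is was not inferred. Reads shared between duplicates can not be separated in these counts.

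Genes were filtered with edgeR's filterByExpr by group, which left 21372 genes, and libraries were scaled with TMM factors. Groups were compared with edgeR 4.0.16 in R 4.3.3 by robust quasi-likelihood F-tests, in a single fit of all 16 libraries with group as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold within each comparison, and a gene past it is described as having risen or fallen. The common biological coefficient of variation was 0.0847. Each dose was compared with DMSO, each pair of doses was compared directly, and a slope on the dose rank (DMSO as the step below 0.1 µM) was tested in a separate fit. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values (counts scaled to 1e6 per library) use the TMM-scaled library sizes and are given as mean ± SD over 4 libraries. No chromosome or read-level data were used.

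Gene lists of pathways, tissues and complexes were written from general knowledge, 48 in all with 1148 names or name patterns, of which 72 matched no gene in the files. The 47 lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01. Camera compares the genes of a list with all other genes. It was repeated with the correlation estimated from the residuals of each list. Fry asks whether the genes of a list moved, on balance, in one direction, and compares them with no other genes. For each list the number of genes past the threshold is given over all genes tested and adjusted over the list alone. The groups, comparisons, tests, lists, the rule for named genes and most alternatives were set before the data were examined.

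Named genes were chosen by rule for each dose against DMSO. The rule takes up to 10 rising and up to 10 falling genes with the largest change among those past the threshold, with at least 1 CPM in the higher group, with all 4 treated libraries on one side of all 4 controls, and with a symbol that is not a clone name. It adds up to 4 members of each list by smallest p, and a fixed set of clock genes, CYP1A1 and PCK1 whatever their p. Not every gene that meets the rule is printed. Genes named for the comparisons between doses were picked from this set, except cry3b, which was named after its values were seen.

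The comparisons of the 3 doses share the DMSO libraries, so unchanged genes correlate between them. The agreement of fold changes was therefore set beside 12 simulations of unchanged groups that keep the real DMSO libraries, and beside fits in which the DMSO libraries were split 2 and 2 between the doses compared (3 splits).

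Alternatives were DESeq2's size factors in edgeR, no filter on low counts, a filter of 1 CPM in at least 4 libraries, each library left out in turn, the edgeR exact test, a fit of the 8 libraries of 2 groups only, DESeq2 1.42.0 (Wald test), the replicate number as a factor, and for lists the estimated correlation and fry. Alternatives added after seeing the data were the share of uniquely aligned reads outside annotated genes as a covariate, and a fit without 3 doubted libraries (0.1 µM replicates 3 and 4, with the largest shares of reads not uniquely aligned, and 1 µM replicate 1, with the lowest total).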

Results

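The data are gene-level read counts from 16 RNA libraries of whole zebrafish larvae, aged 5 days. Animals had been exposed from hour 4 to hour 120 after fertilisation to 0.1% DMSO, the solvent control, or to PCB153 at 0.1, 1 or 10 µM (n = 4 libraries per group). The labels give no clutch, sequencing batch or number of larvae per library. Whether the 4 libraries of a group come from independent clutches is therefore unknown. PCB153 is a persistent polychlorinated biphenyl of the non-dioxin-like kind. Gene counts per library ranged from 13790767 to 15420019 in DMSO, from 12794900 to 15331102 at 0.1 µM, from 8069225 to 15531744 at 1 µM and from 11984848 to 15110922 at 10 µM. The number of genes with a count was between 24579 and 25936 per library. Reads outside annotated genes are here those placed in no counted feature. They made up 33.2 ± 1.92% of the uniquely aligned reads in DMSO (SD, n = 4), 37.0 ± 1.12% at 0.1 µM, 37.3 ± 2.52% at 1 µM and 32.2 ± 0.75% at 10 µM.

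Comparing 0.1 µM PCB153 with DMSO asks which genes changed at the lowest concentration, and the series title names circadian rhythm and metabolism. Genes of the negative limb of the circadian clock were higher at 0.1 µM. NR1D1 (ENSDARG00000033160), a nuclear receptor that represses BMAL1 transcription, rose by 1.41 ± 0.07 log2 units (SE, n = 4 per group, adjusted p = 5.95e-11), from 31.5 ± 3.59 to 83.7 ± 7.19 CPM. PER1 ENSDARG00000056885, which encodes a period protein that inhibits CLOCK and BMAL1, rose by 1.88 ± 0.11 (adjusted p = 3.25e-09), and PER1 ENSDARG00000012499 rose by 0.93 ± 0.06 (adjusted p = 1.98e-09). PER2 rose by 0.74 ± 0.05, PER3 by 0.44 ± 0.06, CRY2 by 0.77 ± 0.05 and CRY1 ENSDARG00000011583 by 0.74 ± 0.08. The smaller rise of CRY1 ENSDARG00000045768, 0.23 ± 0.05 (adjusted p = 0.0155), missed the threshold without DMSO replicate 3 (0.0523), DMSO replicate 4 (0.0621) or 0.1 µM replicate 1 (0.0536).

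Of the 21 clock repressor genes tested, 18 rose and 1 fell at 0.1 µM (18 and 2 adjusted over the list alone), with a median of 0.742. The list test gave an adjusted p of 5.02e-34, and adjusted p = 0.00326 with an estimated correlation. The gene that fell was cry3b, by 0.27 ± 0.07 (adjusted p = 0.0278), a call that was lost without DMSO replicate 2, 3 or 4, or without 0.1 µM replicate 1, 2 or 3 (adjusted p of 0.0521 to 0.113), in a fit of the 8 libraries alone (0.0572) and with the share of reads outside genes as a covariate (-0.30 ± 0.09, adjusted p = 0.16). The clock output list holds the DBP, TEF and HLF genes, which carry the rhythm to other genes, and the ROR genes. Of its 11 genes 6 rose (7 adjusted over the list alone, adjusted p = 0.00326 with an estimated correlation). Among them were dbpb by 1.05 ± 0.08, dbpa by 0.63 ± 0.06, hlfa by 0.42 ± 0.06 and, of the ROR genes, rorcb by 0.64 ± 0.07. The ROR genes rorab, RORA, RORB and rorca differed by 0.02 to 0.13 and were not called. Of 10 genes of light response and DNA repair, called light-response genes below, 8 rose (9 adjusted over the list alone, adjusted p = 0.0074 with an estimated correlation). These included cry5 by 0.67 ± 0.09 and lonrf1 by 0.48 ± 0.06. The repair genes XPC and cpdp differed by 0.26 and 0.11 and were not called. PER2, CRY1 and tefa stand on more than one of these lists. The 6 genes of the clock activator list, which holds the CLOCK, NPAS2 and BMAL genes but not the ROR genes, stayed below the threshold. CLOCK ENSDARG00000003631 differed by 0.14 ± 0.06 (adjusted p = 0.172), CLOCK ENSDARG00000011703 by 0.09 ± 0.06, BMAL1 ENSDARG00000006791 by 0.15 ± 0.07 and BMAL1 ENSDARG00000035732 by 0.02 ± 0.07. CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor, differed by 0.15 ± 0.11 (adjusted p = 0.549).

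Single metabolic and hormone-responsive genes rose at 0.1 µM, while most genes of their lists were not called. FKBP5, a chaperone partner of the glucocorticoid receptor and one of its targets, rose by 1.26 ± 0.09 (adjusted p = 5e-09), KLF9, another target, by 0.70 ± 0.10, and HSD11B2, which inactivates cortisol, by 0.55 ± 0.10 (adjusted p = 0.003). With the covariate HSD11B2 was at 0.55 ± 0.14 (adjusted p = 0.0737), the same fold with a larger error. FKBP5, KLF9 and HSD11B2 were 3 of 15 glucocorticoid-response genes called. The list as a whole was not called (adjusted p = 0.577, median -0.048, mean 0.047). PCK1, which encodes a key enzyme of glucose synthesis, rose by 0.60 ± 0.09, and dio3b, a deiodinase that inactivates thyroid hormone, by 1.01 ± 0.12. They were the only genes called of 21 for gluconeogenesis (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.0319, adjusted p = 0.558 with an estimated correlation) and of 11 for thyroid hormone (1 adjusted over the list alone, list adjusted p = 0.34). For gluconeogenesis 2 genes rose without 0.1 µM replicate 4, without 1 µM replicate 2, without the 3 doubted libraries or with the covariate. The coactivator gene pprc1 rose to 30.8 ± 5.17 CPM from a mean of 11.7 (adjusted p = 9.46e-05). Of 23 hypoxia genes 4 rose (6 higher and 1 lower adjusted over the list alone, 2 higher over all genes without DMSO replicate 1), including PFKFB4 by 1.00 ± 0.11 and hif1al by 0.55 ± 0.07 (list adjusted p = 0.00782, and adjusted p = 0.558 with an estimated correlation). The cone genes guca1c and ARR3 ENSDARG00000098475 rose by 0.72 ± 0.07 and 0.62 ± 0.07, while 4 of 55 phototransduction genes rose and 1 fell (6 and 2 adjusted over the list alone; 2 rose with the covariate) and the list was not called (adjusted p = 0.421). The number falling was 0 in edgeR without DMSO replicate 1 or 3 or 0.1 µM replicate 1 or 3 (3 to 7 at an unadjusted p under 0.05), in a fit of the 8 libraries alone (6 unadjusted), with the covariate (3 unadjusted) and without the 3 doubted libraries (4 unadjusted). It was 2 without 0.1 µM replicate 2 or 1 µM replicate 2 and with DESeq2. In the cholesterol list 4 of 27 genes rose (10 adjusted over the list alone), with ldlrb up by 0.86 ± 0.14 and IDI1 by 0.47 ± 0.10 (0.47 ± 0.14 with the covariate, adjusted p = 0.139). The list had adjusted p = 7.16e-07, and adjusted p = 0.427 with an estimated correlation. The count of cholesterol genes was 2 without DMSO replicate 2, DMSO replicate 3 or 0.1 µM replicate 1, 11 without the 3 doubted libraries, 7 with DESeq2 and 1 with the covariate.

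Among the largest falls at 0.1 µM were those of FOS, GADD45B ENSDARG00000027744 and TXNIP ENSDARG00000070000. FOS, a transcription factor induced within minutes of stimulation, fell by 1.25 ± 0.28 (adjusted p = 0.031), GADD45B ENSDARG00000027744, a stress-induced growth regulator, by 1.22 ± 0.18 (-1.08 ± 0.24 with the covariate, adjusted p = 0.0596) and TXNIP ENSDARG00000070000, an inhibitor of thioredoxin, by 1.07 ± 0.14. FOS missed the threshold without any one of the DMSO libraries or 0.1 µM replicates 1, 2 or 3 (adjusted p of 0.0578 to 0.0863), in a fit of the 8 libraries alone (0.101) and with the covariate (-1.20 ± 0.40, adjusted p = 0.259). At 0.1 µM 7 lists were called downward. The exocrine pancreas list had the lowest median, -0.596 over 30 genes, with 0 genes called. Its list adjusted p was 3.84e-09, and 0.558 with an estimated correlation, and its median was 0.129 with the covariate. Skeletal muscle and lens lists had medians of -0.121 and -0.185 (list adjusted p = 1.68e-05 and 0.00558, and 0.406 and 0.788 with an estimated correlation). Ribosomal protein genes had a median of -0.145 over 85 genes (list adjusted p = 1.62e-21, and adjusted p = 0.406 with an estimated correlation). Of these, RPS2 fell by 0.23 ± 0.06 (adjusted p = 0.0464) and RPL10A by 0.30 ± 0.08 (adjusted p = 0.047), while 51 fell and 1 rose when adjusted over the list alone. Both single-gene calls were lost without DMSO replicate 2, 3 or 4 or without 0.1 µM replicate 1, 2 or 3, in a fit of the 8 libraries alone (0.0906 and 0.064) and with the covariate (-0.14 ± 0.08 and -0.14 ± 0.10, adjusted p = 0.551 and 0.69). The number of ribosomal genes that fell in edgeR was 0 without DMSO replicate 2, 3 or 4 or 0.1 µM replicate 1, 2 or 3 (35 to 58 at an unadjusted p under 0.05), 0 in a fit of the 8 libraries alone (57 unadjusted) and 0 with the covariate (1 unadjusted). It was 0 without 10 µM replicate 1 or 4 (56 unadjusted), 1 without DMSO replicate 1, 1 µM replicate 4, 10 µM replicate 2 or 3 or with the exact test, and 4 without 1 µM replicate 1. It was 22 without 0.1 µM replicate 4, 15 without the 3 doubted libraries and 10 with DESeq2. The share of reads outside annotated genes was higher in these 4 libraries than in every DMSO library (36.2% to 38.6% against 31.4% to 35.5%, exact permutation p = 0.0286, 2-sided, adjusted to 0.0858 over 6 tests).

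In all, 734 of 21372 genes changed at 0.1 µM, 491 upward and 243 downward, of which 30 changed at least 2-fold. For 684 of the 734 the treated libraries lay entirely on one side of the controls, as did 9.99% of all genes, where chance gives 2.86%. The count was 411 without DMSO replicate 3, 455 without DMSO replicate 4, 1117 without 0.1 µM replicate 4, 487 in a fit of the 8 libraries alone, and 1165 without the 3 doubted libraries. With the share of reads outside genes as a covariate 207 genes passed the threshold, 192 of them among the 734.

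**Figure D1:**
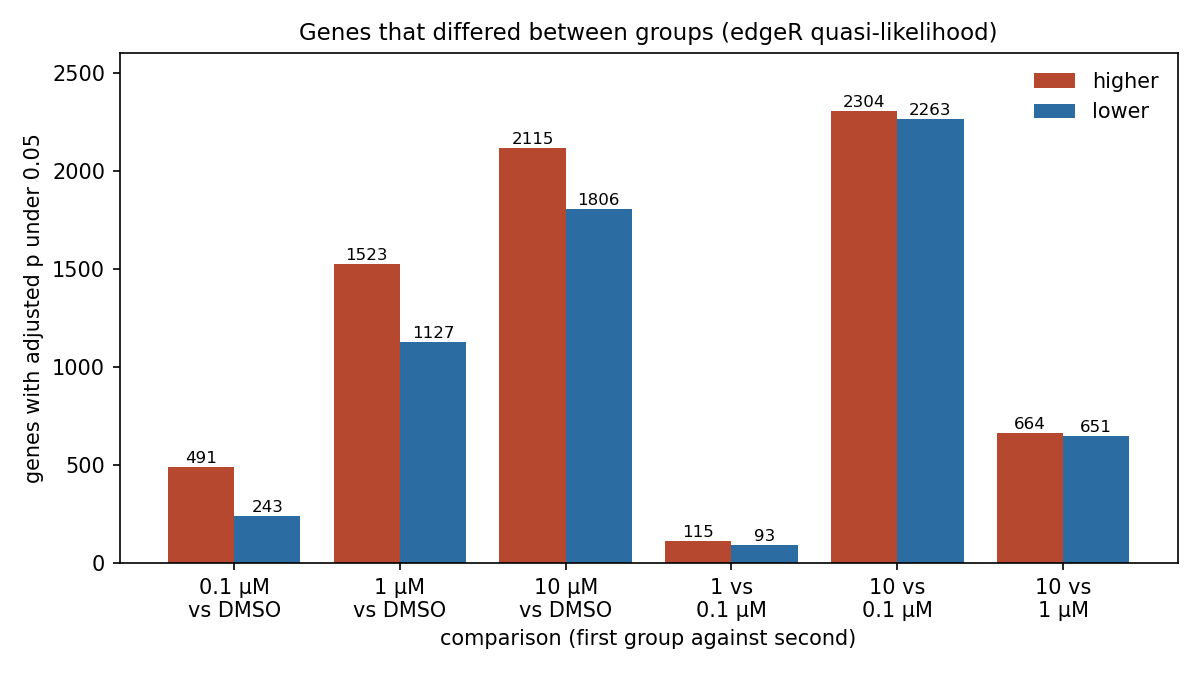
Bars give the number of genes with adjusted p under 0.05 that were higher (red) or lower (blue) in the first group of each comparison (edgeR quasi-likelihood, n = 4 libraries per group). Against DMSO the counts were 491 and 243 at 0.1 µM, 1523 and 1127 at 1 µM, and 2115 and 1806 at 10 µM.

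Comparing 1 µM PCB153 with DMSO asks which genes changed at the middle concentration. The clock repressors were again among the largest rises. PER1 ENSDARG00000056885 rose by 2.23 ± 0.11 (adjusted p = 1.5e-10), NR1D1 by 1.80 ± 0.07 (adjusted p = 3.77e-13), PER1 ENSDARG00000012499 by 1.13 ± 0.06, CRY1 ENSDARG00000011583 by 0.99 ± 0.08, PER2 by 0.90 ± 0.05 and PER3 by 0.71 ± 0.06 (n = 4 per group). Of 21 clock repressor genes 18 rose and cry3b fell (18 and 1 adjusted over the list alone), with a median of 0.877 and adjusted p = 0.00498 with an estimated correlation. Of the clock output genes 7 of 11 rose (9 adjusted over the list alone), with dbpb up from 24.6 ± 1.09 to 60.9 ± 2.84 CPM, dbpa at 0.80 ± 0.06 and tefb at 0.68 ± 0.07, and adjusted p = 0.00498 with an estimated correlation. Of the light-response genes 9 of 10 rose (9 adjusted over the list alone, adjusted p = 0.0193 with an estimated correlation). Of 6 clock activators npas2 rose, by 0.29 ± 0.08 (adjusted p = 0.0215; 2 rose adjusted over the list alone). Its call was lost without DMSO replicate 1, 3 or 4 or 1 µM replicate 2 (adjusted p of 0.0517 to 0.085) and with the covariate (0.21 ± 0.11, adjusted p = 0.324). CLOCK ENSDARG00000003631 differed by 0.16 ± 0.06 (adjusted p = 0.0624), and CYP1A1 by 0.13 ± 0.12 (adjusted p = 0.537).

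Genes of oxygen sensing and of glucose synthesis were higher at 1 µM, and some genes of oxidative phosphorylation were lower. PFKFB4, which sets the level of a regulator of glycolysis, rose by 1.64 ± 0.12 (adjusted p = 1.02e-07), and with it 10 of 23 hypoxia genes rose (12 adjusted over the list alone, list adjusted p = 2.38e-08). That list had adjusted p = 0.19 with an estimated correlation. Its members hif1al, EGLN2 and EPAS1 ENSDARG00000008697 rose by 0.86 ± 0.07, 0.60 ± 0.09 and 0.48 ± 0.07. PCK1 rose by 0.95 ± 0.09 and FOXO1 ENSDARG00000099555, a transcription factor of the fasting response, by 0.64 ± 0.07. Of 21 gluconeogenesis genes 7 rose (8 adjusted over the list alone, list adjusted p = 0.000646, adjusted p = 0.227 with an estimated correlation), and 4 did without DMSO replicate 3 or without 1 µM replicate 3. Of 99 nuclear genes of oxidative phosphorylation 9 fell (3 adjusted over the list alone), with a median of -0.125 (list adjusted p = 1.32e-07, adjusted p = 0.361 with an estimated correlation). That count was 3, 5 and 4 without DMSO replicates 2, 3 and 4, 4, 4 and 20 without 1 µM replicates 1, 2 and 3, 4 without the 3 doubted libraries and 1 with the covariate. The lists of glycolysis and fatty acid oxidation were not called (adjusted p = 0.998 and 0.738), with medians of -0.028 and -0.043 and means of 0.009 and 0.063. FKBP5 rose by 1.54 ± 0.09 and KLF9 by 1.31 ± 0.10, and in all 4 of 15 glucocorticoid-response genes rose and 1 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.0411, adjusted p = 0.684 with an estimated correlation). The number falling was 2 without 0.1 µM replicate 2 or 4, in a fit of the 8 libraries alone, with the exact test of edgeR and with DESeq2, and 0 with the covariate (1 unadjusted). LPIN1, which makes diacylglycerol, rose from 235 ± 10.9 to 622 ± 179 CPM (adjusted p = 0.000847) and UCP2, a mitochondrial carrier, rose by 0.59 ± 0.08. NR1I2, the pregnane X receptor that senses foreign compounds, rose by 0.81 ± 0.09, and cyp2k6, a cytochrome P450 gene, by 2.18 ± 0.45 (adjusted p = 0.00505; 2.1 ± 0.61 with the covariate, adjusted p = 0.0677). The gene cyp2aa9 fell by 2.09 ± 0.56 (adjusted p = 0.0163), and not past the threshold without 1 µM replicate 3 (0.0522) or with the covariate (-1.63 ± 0.76, adjusted p = 0.249). Its counts were low, with log2 CPM from -0.34 to 0.39 in DMSO and from -1.71 to -1.29 at 1 µM (prior count of 2). These 3 genes belong to the list of 42 genes of the cytochrome P450 families 2 and 3, counted with the pregnane X receptor, of which 6 rose and 2 fell (6 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.455). The number falling was 1 without 1 µM replicate 3, in a fit of the 8 libraries alone and with DESeq2, and 0 with the covariate (4 unadjusted).

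Genes of skin, skeleton and cell division were lower at 1 µM. In the epidermis list 10 of 28 genes fell (12 adjusted over the list alone, list adjusted p = 1.63e-06), with icn down by 0.67 ± 0.09 and krt1-19d by 0.44 ± 0.06. This list had adjusted p = 0.227 with an estimated correlation, and 3 of its genes fell with the covariate. In the cartilage and bone matrix list 11 of 34 fell (15 adjusted over the list alone, list adjusted p = 4.92e-07, adjusted p = 0.292 with an estimated correlation). Its members SOX9 ENSDARG00000043923, a master regulator of cartilage, and COL10A1 ENSDARG00000054753, a collagen of hypertrophic cartilage and bone, fell by 0.50 ± 0.10 and 0.60 ± 0.11 (the latter -0.56 ± 0.16 with the covariate, adjusted p = 0.0578). That count was 5 without DMSO replicate 2, 7 without DMSO replicate 3 or 4, 6 without 1 µM replicate 1, 7 without 1 µM replicate 4, 6 without the 3 doubted libraries and 5 with the covariate. The chemokine receptor genes CXCR4 ENSDARG00000057633 and ENSDARG00000041959 fell by 1.19 ± 0.22 and 0.76 ± 0.14 (the latter -0.63 ± 0.20 with the covariate, adjusted p = 0.0695). PTGS2 ENSDARG00000004539, an enzyme of prostaglandin synthesis, fell by 0.97 ± 0.18 (-0.89 ± 0.25 with the covariate, adjusted p = 0.0588). The leukocyte and inflammation lists were not called (adjusted p = 0.0996 and 0.209). Of 26 leukocyte genes 3 fell (3 adjusted over the list alone). Of 24 inflammation genes 6 fell and 1 rose (6 and 2 adjusted over the list alone). With the covariate 1 leukocyte gene fell, and 0 inflammation genes passed in edgeR (6 lower unadjusted). The number of falling inflammation genes was 3 without DMSO replicate 1 or 1 µM replicate 3. Of the cell cycle genes 7 of 38 fell (18 adjusted over the list alone), with BIRC5 down by 0.92 ± 0.21 (-0.98 ± 0.29 with the covariate, adjusted p = 0.0526) and plk1 by 0.58 ± 0.12. The list median was -0.423, with adjusted p = 1.05e-10 by the preset test and adjusted p = 0.59 with an estimated correlation. The count of cell cycle genes was 17 without 0.1 µM replicate 2, 24 in a fit of the 8 libraries alone, 17 with the exact test of edgeR, 16 with DESeq2 and 1 with the covariate.

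At 1 µM 2650 of 21372 genes changed, 1523 upward and 1127 downward, and 132 changed at least 2-fold. Libraries did not overlap between the groups for 2356 of the 2650 and for 19.2% of all genes, where chance gives 2.86%. With the share of reads outside genes as a covariate 1076 genes passed the threshold.

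**Figure D2:**
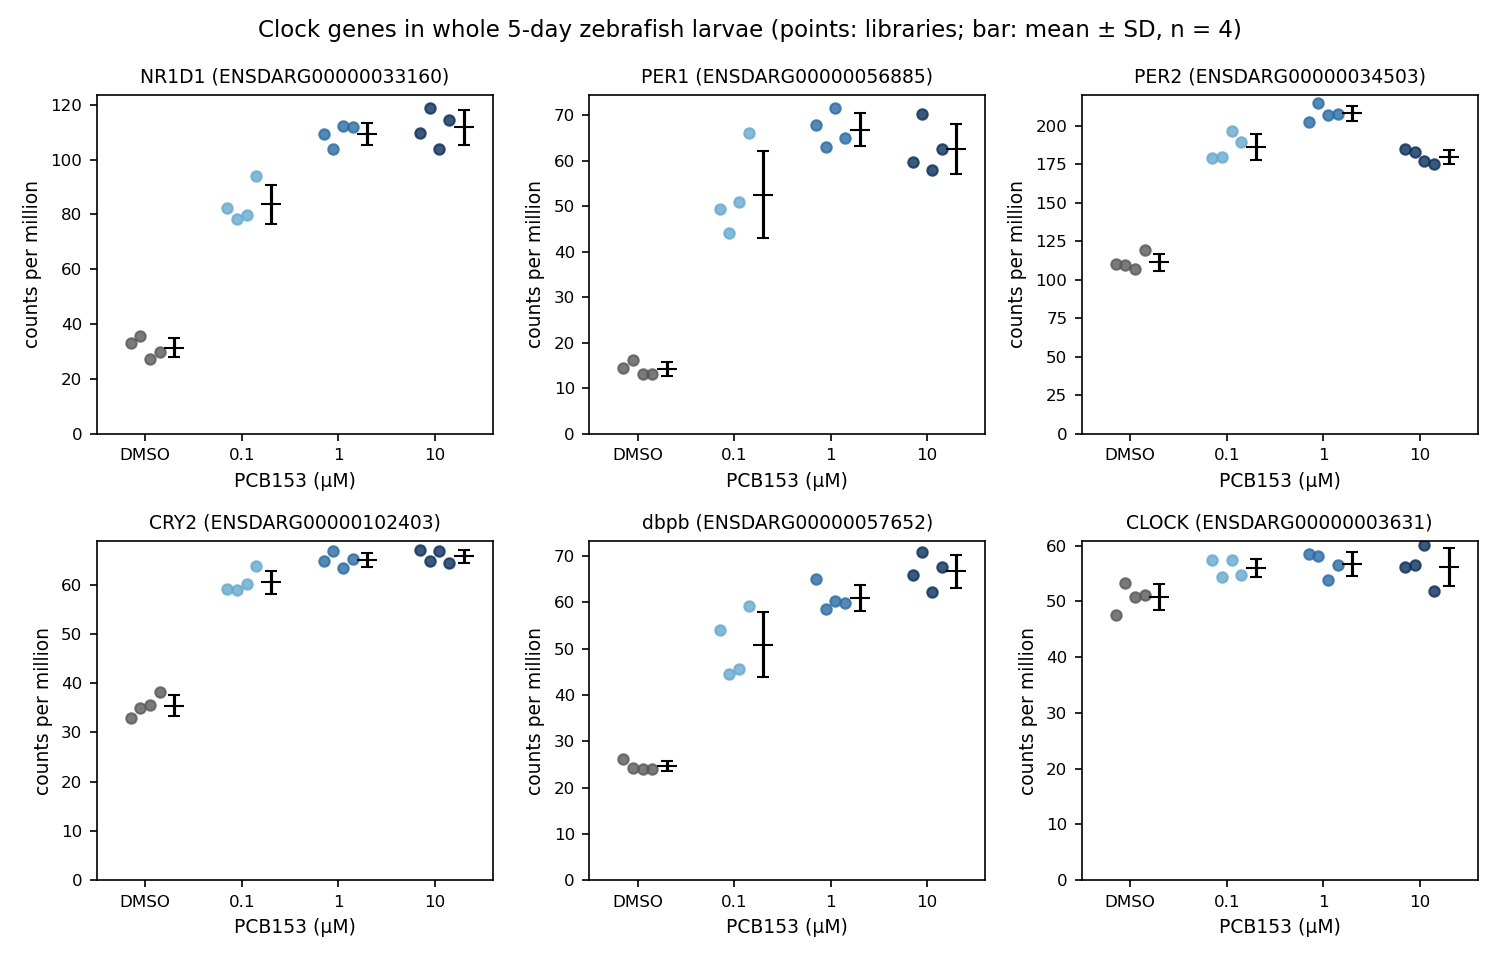
Each panel plots CPM (TMM-scaled) of a gene against the PCB153 concentration in µM, with points for the 4 libraries of a group and a bar for their mean ± SD. The 12 exposed libraries lie above all 4 DMSO libraries for NR1D1, PER1 ENSDARG00000056885, PER2, CRY2 and dbpb, while CLOCK ENSDARG00000003631 differed by 0.14 to 0.16 log2 units.

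Comparing 10 µM PCB153 with DMSO asks which genes changed at the highest concentration. PER1 ENSDARG00000056885 rose by 2.13 ± 0.11 (adjusted p = 1.96e-10), NR1D1 by 1.83 ± 0.07 (adjusted p = 2.45e-13), nfil3-6, a transcriptional repressor of the clock, by 2.00 ± 0.11 and CRY2 by 0.89 ± 0.05 (n = 4 per group). NR1D1 reached 112 ± 6.43 CPM. Of 21 clock repressor genes 19 rose (19 adjusted over the list alone), with a median of 1.005 and adjusted p = 0.00678 with an estimated correlation. The gene cry3b fell by 0.21 ± 0.07 (adjusted p = 0.0303), and not past the threshold without DMSO replicate 2, 3 or 4 or 10 µM replicate 2, 3 or 4 (0.0565 to 0.112) or with the covariate (-0.21 ± 0.07, adjusted p = 0.0513). Clock output genes rose in 7 of 11 cases (10 adjusted over the list alone, adjusted p = 0.00678 with an estimated correlation), dbpb by 1.44 ± 0.08. Light-response genes rose in 9 of 10 cases (10 adjusted over the list alone, adjusted p = 0.0313 with an estimated correlation). Among 6 clock activators bmal2 fell by 0.48 ± 0.10 (adjusted p = 0.00204) and npas2 rose by 0.28 ± 0.08 (adjusted p = 0.0194). The npas2 call was lost without DMSO replicate 1 or 4 or 10 µM replicate 1, 2 or 3 (0.0515 to 0.0615). CLOCK ENSDARG00000003631 differed by 0.15 ± 0.06 (adjusted p = 0.0683, 0.0343 without 10 µM replicate 4 and 0.049 with the covariate), and BMAL1 ENSDARG00000035732 by -0.13 ± 0.07 (adjusted p = 0.185). CYP1A1 differed by 0.24 ± 0.11 (adjusted p = 0.159).

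At 10 µM genes of the hypoxia, glucose, fatty acid oxidation, glucocorticoid and insulin lists rose. Of 23 hypoxia genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with PFKFB4 up by 1.82 ± 0.12 and hif1al by 1.17 ± 0.07. The list test gave adjusted p = 2.15e-10, and adjusted p = 0.0793 with an estimated correlation. Of 21 gluconeogenesis genes 10 rose and 1 fell (10 and 2 adjusted over the list alone, list adjusted p = 3.85e-05, adjusted p = 0.097 with an estimated correlation), with PCK1 up by 1.34 ± 0.09, from 421 ± 18.6 to 1067 ± 64.1 CPM, creb3l3b by 0.94 ± 0.11 and GPT ENSDARG00000055642 by 0.80 ± 0.10. In edgeR 0 of them fell without DMSO replicate 2 or 10 µM replicate 1 or 2 (2 or 3 at an unadjusted p under 0.05). The count was 2 without DMSO replicate 3, 0.1 µM replicate 2 or 4 or the 3 doubted libraries, and in a fit of the 8 libraries alone. Of 38 genes of fatty acid oxidation 12 rose and 1 fell (12 and 2 adjusted over the list alone, adjusted p = 0.00183 for the list and adjusted p = 0.16 with an estimated correlation). Among them the mitochondrial carrier genes ucp3 and UCP2 rose by 1.64 ± 0.16 and 0.85 ± 0.08, and PDK2 ENSDARG00000020876, which shuts off entry of pyruvate into the citric acid cycle, by 1.08 ± 0.14. Glycolysis genes rose in 13 of 35 cases (15 adjusted over the list alone, list adjusted p = 3.46e-05, adjusted p = 0.127 with an estimated correlation), among them PFKM ENSDARG00000014179 by 0.61 ± 0.08. Of 15 glucocorticoid-response genes 7 rose (8 adjusted over the list alone), FKBP5 by 1.58 ± 0.09, HSD11B2 by 0.91 ± 0.10 and tsc22d3 by 0.51 ± 0.08, and KLF9 from 118 ± 7.61 to 334 ± 42.5 CPM. That list had adjusted p = 3.37e-06, and adjusted p = 0.127 with an estimated correlation. Of 21 insulin and IGF genes 9 rose and 1 fell (10 and 3 adjusted over the list alone, list adjusted p = 0.00667, adjusted p = 0.127 with an estimated correlation), with igfbp1b, which binds insulin-like growth factors, up by 1.96 ± 0.32 and IRS2 ENSDARG00000075282, an insulin receptor substrate, by 1.00 ± 0.10. The deiodinase gene dio3b rose by 1.93 ± 0.12.

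Photoreceptor and nervous system genes were higher at 10 µM. Of 55 phototransduction genes 23 rose (24 adjusted over the list alone, list adjusted p = 2.15e-10), guca1c by 1.36 ± 0.07, GUCA1A ENSDARG00000100747 by 1.26 ± 0.14, CNGA3 ENSDARG00000012297 by 1.18 ± 0.12 and ARR3 ENSDARG00000098475 by 1.00 ± 0.07. The list had adjusted p = 0.0793 with an estimated correlation. Of 38 neuronal genes 13 rose (15 adjusted over the list alone, list adjusted p = 1.02e-05, adjusted p = 0.12 with an estimated correlation), including GAD2 by 0.42 ± 0.06 and GAD1 ENSDARG00000027419 by 0.37 ± 0.06, whose products make the transmitter GABA. GLUL ENSDARG00000099776, a glial enzyme that makes glutamine, rose by 0.77 ± 0.07. Of 22 glial genes 8 rose (10 adjusted over the list alone, list adjusted p = 0.00464, adjusted p = 0.12 with an estimated correlation), and 5 did without 10 µM replicate 1.

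Genes of cell division, skeleton, skin and liver were lower at 10 µM. Of 38 cell cycle genes 21 fell (27 adjusted over the list alone), with a median of -0.561. The mitotic kinase genes aurka and plk1 fell by 1.02 ± 0.17 and 0.70 ± 0.12 and the spindle checkpoint gene bub1bb by 0.76 ± 0.16. The list had adjusted p = 6.65e-14, and adjusted p = 0.229 with an estimated correlation, and the count was 13 without DMSO replicate 2, 10 without 10 µM replicate 1 and 12 without 10 µM replicate 2. Of 34 cartilage and bone matrix genes 18 fell and 1 rose (20 and 2 adjusted over the list alone, list adjusted p = 1.01e-08, adjusted p = 0.12 with an estimated correlation). In this list 2 rose without 0.1 µM replicate 2 or 4, 1 µM replicate 3 or the 3 doubted libraries, and also in a fit of the 8 libraries alone, with the exact test of edgeR and with DESeq2. COL10A1 ENSDARG00000054753 fell by 0.82 ± 0.11, SOX9 ENSDARG00000043923 by 0.66 ± 0.10 and COL2A1 ENSDARG00000011407, the main collagen of cartilage, by 0.39 ± 0.07. Of 28 epidermis genes 14 fell and 2 rose (15 and 2 adjusted over the list alone, list adjusted p = 0.000115, adjusted p = 0.185 with an estimated correlation), with the keratin gene krt4 down by 0.53 ± 0.08. Only 1 epidermis gene rose without DMSO replicate 1, 2 or 4, without 10 µM replicate 2 or 4 or with the covariate. In a fit of the 8 libraries alone 4 rose. Of 25 liver genes 6 fell and 1 rose (6 and 1 adjusted over the list alone, list adjusted p = 0.0113, adjusted p = 0.517 with an estimated correlation), with tfa, the gene of the iron carrier transferrin, down by 0.62 ± 0.13 and fabp10a by 0.33 ± 0.08. The number of falling liver genes was 3 without DMSO replicate 3 or without 10 µM replicate 2.

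Of 55 genes of conjugation and transport of foreign compounds 13 fell and 6 rose at 10 µM (17 and 7 adjusted over the list alone), and the list was called downward (adjusted p = 0.02, adjusted p = 0.229 with an estimated correlation). The number falling was 6 without 10 µM replicate 1 and 21 in a fit of the 8 libraries alone, and 3 rose without 10 µM replicate 4. Of 42 genes of the cytochrome P450 families 2 and 3, counted with the pregnane X receptor, 7 rose and 5 fell (7 and 8 adjusted over the list alone), and that list was not called (adjusted p = 0.69). Of these 4 rose without DMSO replicate 2, 3 or 4, without 10 µM replicate 1 or 4, without the filter on low counts or with the covariate, and 3 rose without 10 µM replicate 2. The number falling was 3 without DMSO replicate 3 or 10 µM replicate 2. The cytochrome P450 gene cyp2k6 had the largest rise of the named genes, 3.23 ± 0.40 (adjusted p = 6.97e-05), from 0.922 ± 0.522 to 8.81 ± 2.71 CPM, with 10 µM replicate 4 below the other treated libraries. CYP24A1, which degrades vitamin D, rose by 1.83 ± 0.24 and NR1I2 by 0.86 ± 0.09. The glutathione transferase gene GSTM3 ENSDARG00000029473 fell by 1.97 ± 0.28 (adjusted p = 3.25e-05) and the low-count gene cyp2aa9 by 1.97 ± 0.54. The apolipoprotein B gene apobb.2 fell by 2.48 ± 0.55 (adjusted p = 0.00806).

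At 10 µM 3921 of 21372 genes changed, 2115 upward and 1806 downward, and 254 changed at least 2-fold. Libraries did not overlap for 3480 of the 3921 and for 24.9% of all genes, where chance gives 2.86%. The count was 2580 without 10 µM replicate 2. The list tests with the preset correlation called 17 of 47 lists at 0.1 µM (10 upward), 17 at 1 µM (10 upward) and 22 at 10 µM (16 upward). With an estimated correlation 3 were called at each dose, those of the clock repressors, the clock output and the light response.

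**Figure D3:**
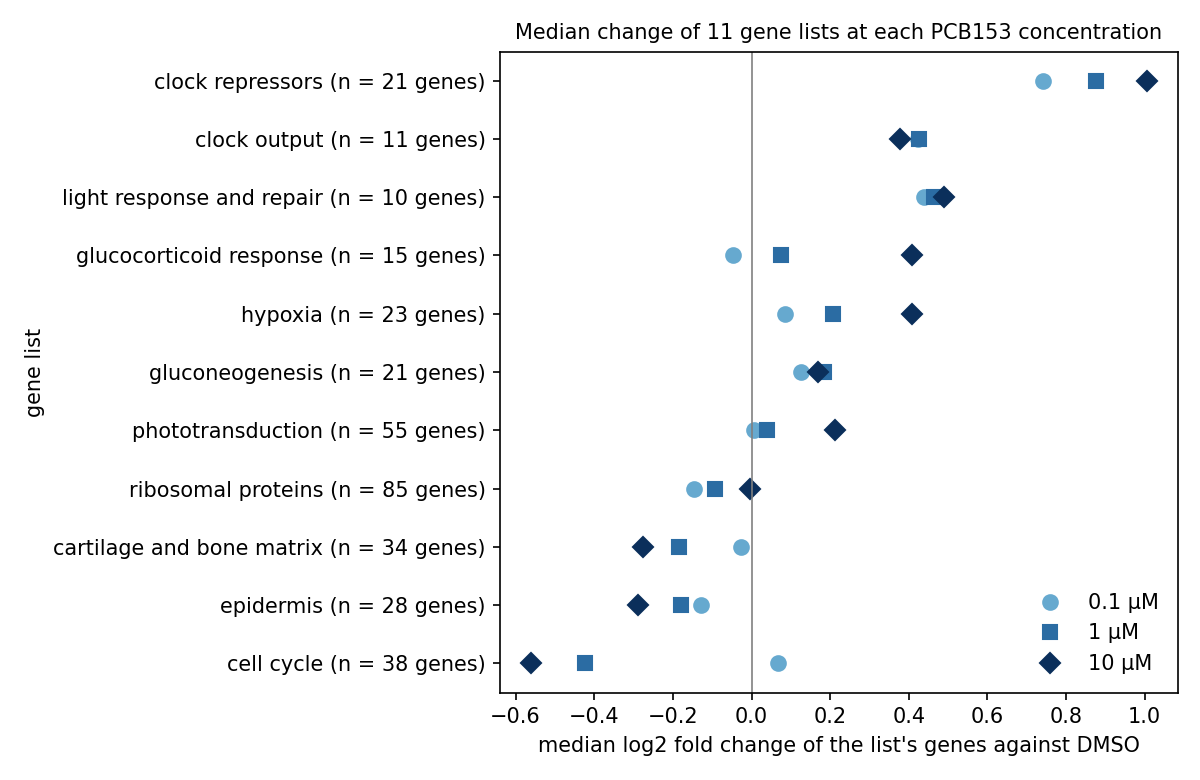
Points give the median log2 fold change against DMSO over the tested genes of 11 lists at 0.1, 1 and 10 µM. The clock repressor medians were 0.742, 0.877 and 1.005, and the cell cycle medians were 0.067, -0.423 and -0.561.

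The comparison of 1 with 0.1 µM tests whether these doses differ. KLF9 was higher at 1 µM by 0.61 ± 0.10 (adjusted p = 0.00969), EGLN2, a sensor of oxygen, by 0.55 ± 0.09 (adjusted p = 0.00969), FOXO1 ENSDARG00000099555 by 0.42 ± 0.07 (adjusted p = 0.00938) and NR1D1 by 0.39 ± 0.07 (adjusted p = 0.0128). The epidermal gene icn was lower by 0.52 ± 0.09 (adjusted p = 0.0119). In a fit of the 8 libraries alone these 5 genes had adjusted p of 0.0516 to 0.101, KLF9 and EGLN2 had 0.0732 and 0.053 without the 3 doubted libraries, and NR1D1 had 0.0507 without 0.1 µM replicate 2 and 0.0542 without 0.1 µM replicate 3. In all 208 genes differed, 115 higher and 93 lower, and 7 did in the fit of the 8 libraries alone. The direction was mostly upward at 55.3%, but 45.1% were higher without the filter on low counts, 47.8% with the exact test of edgeR and 34.4% without the 3 doubted libraries. The count was 131 without DMSO replicate 1, 377, 32, 32 and 630 without 0.1 µM replicates 1 to 4, 40, 431, 36 and 51 without 1 µM replicates 1 to 4, and 133 without 10 µM replicate 1. It was 401 without the doubted libraries, 506 with the exact test of edgeR and 586 with DESeq2.

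The comparison of 10 with 0.1 µM asks what differed between the lowest and highest dose. PCK1 was higher at 10 µM by 0.74 ± 0.09 (adjusted p = 4.94e-05), hif1al by 0.62 ± 0.07, GPT ENSDARG00000055642, which links alanine to glucose synthesis, by 1.00 ± 0.10, KLF9 by 0.80 ± 0.10, guca1c by 0.64 ± 0.07, TP53INP1 by 1.02 ± 0.10 and cyp2k6 by 2.82 ± 0.39. GSTM3 ENSDARG00000029473 differed by -2.13 ± 0.27 (adjusted p = 3.72e-05). Cell cycle genes were lower in 29 of 38 cases (30 adjusted over the list alone) and phototransduction genes higher in 24 of 55 (33 adjusted over the list alone). NR1D1 was higher by 0.42 ± 0.07 (adjusted p = 0.000342; 0.23 ± 0.10 with the covariate, adjusted p = 0.212), as were 10 of 21 clock repressor genes (12 adjusted over the list alone), while PER2 differed by -0.05 ± 0.05 (adjusted p = 0.51) and PER3 by 0.06 ± 0.06 (adjusted p = 0.446). In all 4567 genes differed, 2304 higher and 2263 lower, of which 200 at least 2-fold. The 4 libraries at 0.1 µM had 36.2% to 38.6% of their unique reads outside genes and those at 10 µM 31.7% to 33.3%, and with this share as a covariate 275 genes differed, among them 2 clock repressor genes and 1 phototransduction gene. With the covariate 0 cell cycle genes passed in edgeR and 21 had an unadjusted p under 0.05. Without 10 µM replicate 2 the count of all genes was 2961, and cell cycle genes numbered 18 without 0.1 µM replicate 2, 17 without 10 µM replicate 1, 16 without 10 µM replicate 2 and 13 in a fit of the 8 libraries alone.

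The comparison of 10 with 1 µM asks what the last step in dose added. The genes guca1c and ARR3 ENSDARG00000098475 were higher at 10 µM by 0.50 ± 0.07 (adjusted p = 0.000241) and 0.51 ± 0.07 (adjusted p = 0.00017), and 20 of 55 phototransduction genes were higher (30 higher and 1 lower adjusted over the list alone). HSP90AA1 ENSDARG00000024746, a heat shock chaperone, was higher by 1.14 ± 0.11 and dio3b by 0.91 ± 0.12. The genes pprc1 and GSTM3 ENSDARG00000029473 differed by -1.37 ± 0.15 and -2.16 ± 0.28. NR1D1 differed by 0.03 ± 0.07 (adjusted p = 0.848), and PER2 by -0.21 ± 0.05 (adjusted p = 0.017), though not past the threshold without 1 µM replicate 2 (0.0564), without 10 µM replicate 4 (0.0525) or with the covariate (-0.14 ± 0.08, adjusted p = 0.607). Of 21 clock repressor genes 3 were higher and 2 lower (4 and 2 adjusted over the list alone). With the covariate 0 passed in edgeR, with 1 higher and 1 lower at an unadjusted p under 0.05. The number higher was 5 without 1 µM replicate 1 or without the 3 doubted libraries, and 1 without 1 µM replicate 2 or 10 µM replicate 2. The number lower was 0 without 1 µM replicate 2, and 1 without 1 µM replicate 3 or 4, without any one 10 µM replicate, without the filter on low counts or with the exact test of edgeR. In all 1315 genes differed, 664 higher and 651 lower. With the covariate 53 differed, guca1c, ARR3 ENSDARG00000098475 and dio3b were at 0.31 ± 0.10, 0.37 ± 0.10 and 0.72 ± 0.18, not past the threshold (adjusted p of 0.139 to 0.254), and 0 phototransduction genes passed in edgeR, with 12 at an unadjusted p under 0.05. The count of all genes was 528 without 1 µM replicate 2, 843 without 1 µM replicate 4, 628 without 10 µM replicate 1, 543 without 10 µM replicate 2 and 830 without 10 µM replicate 4. The phototransduction count was 10, 13, 10 and 11 without 1 µM replicates 2 and 4 and 10 µM replicates 1 and 2.

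A slope on dose rank asks which genes rose or fell on average with the rank of the dose, from DMSO to 10 µM. A gene that changed at a single step can also pass, so a slope does not show a change at each step. Among rising genes the slope per step was 0.38 ± 0.03 log2 units for hif1al (adjusted p = 1.96e-08), 0.44 ± 0.03 for PCK1 (adjusted p = 1.96e-08), 0.42 ± 0.03 for guca1c, 0.51 ± 0.04 for KLF9 and 0.28 ± 0.03 for UCP2. Among falling genes it was -0.34 ± 0.05 for aurka, -0.22 ± 0.03 for SOX9 ENSDARG00000043923 and -0.19 ± 0.03 for krt4 (n = 16 libraries). Of 21372 genes 3851 had a slope past the threshold, 2034 upward and 1817 downward.

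**Figure D4:**
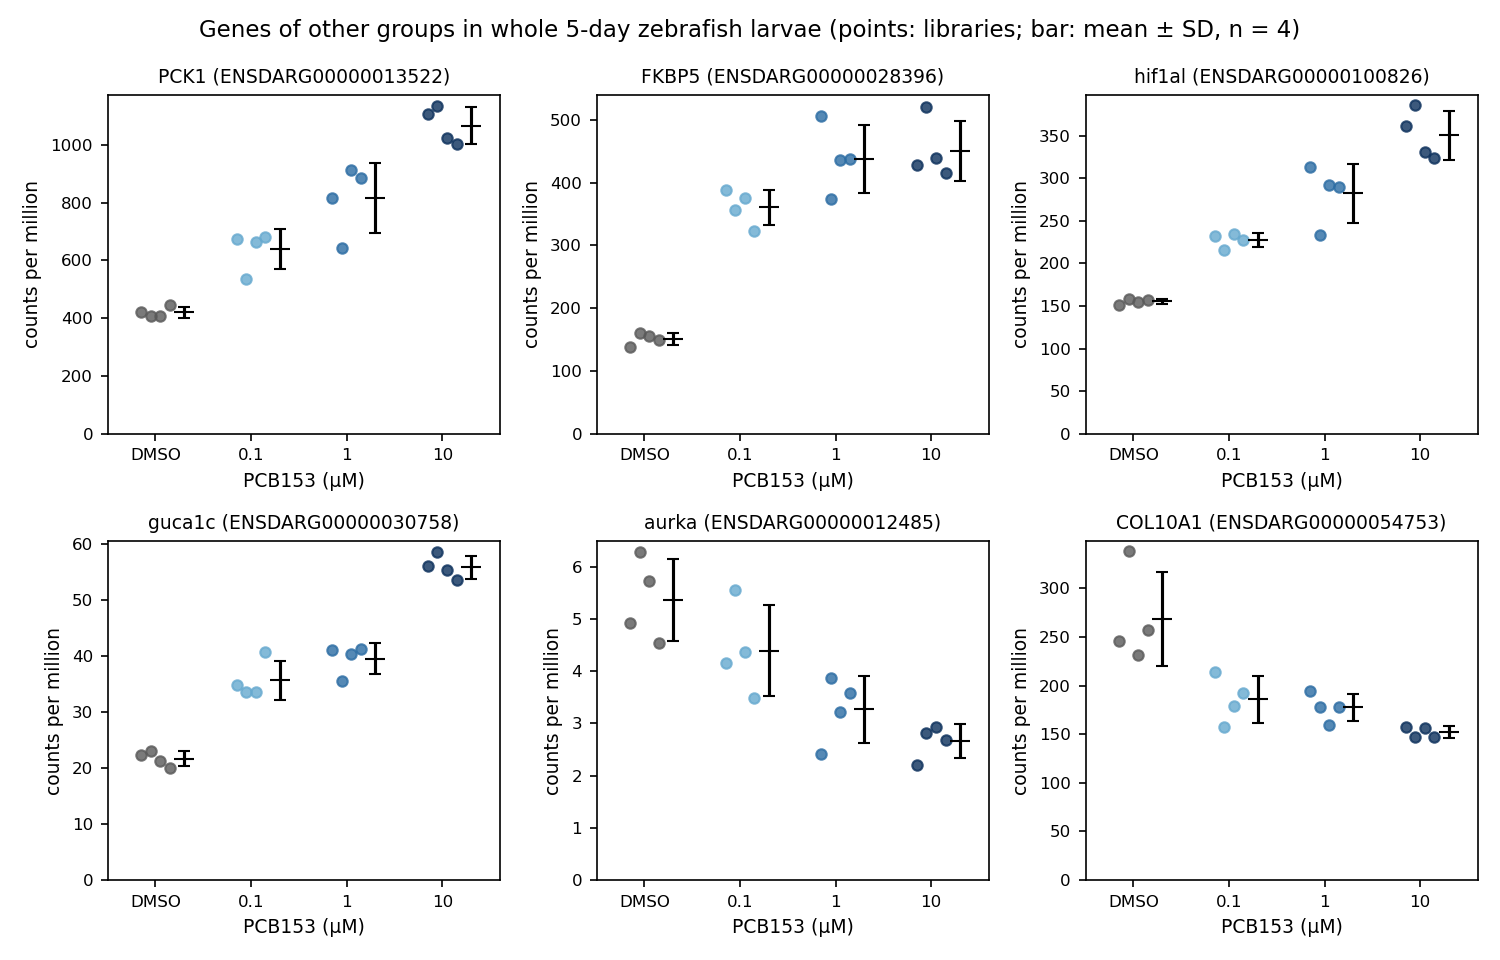
Each panel plots CPM (TMM-scaled) of a gene against the PCB153 concentration in µM, with points for the 4 libraries of a group and a bar for their mean ± SD. PCK1 went from 421 CPM in DMSO to 1067 at 10 µM, and COL10A1 ENSDARG00000054753 from 268 to 152.

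Genes shared between doses were mostly higher. At all 3 doses 267 genes rose and 87 fell, among them 18 of 21 clock repressor genes, 6 of 11 clock output genes and 8 of 10 light-response genes that rose. For 0.1 and 1 µM 416 genes rose at both and 177 fell at both, and the fold changes had a correlation of 0.626 across genes, which are not independent replicates. Unchanged groups against the same DMSO libraries gave a correlation of 0.496 and a mean of 0.08 shared calls in simulations. DMSO libraries split between the doses gave 0.369, with means of 151.5 genes higher and 39 lower at both. The covariance was 0.04, against 0.0158 simulated and 0.0286 with split controls. The simulations drew the treated libraries gene by gene, so they lack variation of whole libraries that moves many genes together. One such difference is the share of reads outside genes, whose mean was higher at 0.1 and 1 µM than in DMSO. For 1 and 10 µM 899 genes rose at both and 570 fell at both (0.08 simulated, 416 and 153.7 with split controls), with a correlation of 0.641 against 0.495 simulated and 0.449 with split controls, and a covariance of 0.0585 against 0.0161 and 0.0467. For 0.1 and 10 µM 273 genes rose at both, 91 fell at both and 15 changed in opposite directions (0.25 shared calls simulated, and 113.3 higher and 15.5 lower at both with split controls). Their correlation of 0.327 lay below the 0.505 of unchanged groups and was 0.141 with split controls, while the covariance of 0.0238 lay above the simulated 0.016 and was 0.0122 with split controls.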

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

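Tests chosen only after the results were seen were those of sequencing depth, hour of collection, cell types and the read share for the clock genes, and the fits with a covariate or without 3 libraries; the splits and the fits with a library left out were planned.

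Clock repressor genes were higher at all 3 doses than in DMSO. With any single DMSO library left out, at least 16 of 21 stayed called upward at every dose. This argues against any single control library as the cause, and does not test several together. With the share of reads outside genes as a covariate 16 were called upward at 0.1 µM and 17 at 1 µM, the doses where the share was higher. These counts argue against that share as the whole cause. Another hour of collection for the control larvae may produce such a pattern, because these genes cycle through the day; the CLOCK and BMAL1 genes differed by at most 0.16 log2 units. Of the other activators bmal2 fell by 0.48 at 10 µM and differed by 0.07 and -0.11 at 0.1 and 1 µM, where the repressors rose as well. The activator npas2 differed by 0.14 at 0.1 µM (adjusted p = 0.383) and rose by 0.29 and 0.28 at 1 and 10 µM. At 1 µM that call was lost without DMSO replicate 1, 3 or 4 or 1 µM replicate 2 (adjusted p of 0.0517 to 0.085) and with the covariate (0.21 ± 0.11, adjusted p = 0.324), and at 10 µM without DMSO replicate 1 or 4 or 10 µM replicate 1, 2 or 3 (0.0515 to 0.0615). These values do not settle it, since activators can be near a turning point. The labels give no hour of collection, so this and an effect of PCB153 cannot be told apart here. An effect of the compound on the clock is a hypothesis.

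The 85 ribosomal protein genes had a median of -0.145 at 0.1 µM, and 2 of them passed the threshold (list adjusted p = 1.62e-21, but adjusted p = 0.406 with an estimated correlation). In edgeR 0 passed with the covariate (1 at an unadjusted p under 0.05), in a fit of the 8 libraries alone (57 unadjusted), and without DMSO replicate 2, 3 or 4 or 0.1 µM replicate 1, 2 or 3 (35 to 58 unadjusted) or 10 µM replicate 1 or 4 (56 unadjusted), while 1 passed without DMSO replicate 1, 1 µM replicate 4 or 10 µM replicate 2 or 3 or with the exact test, 4 without 1 µM replicate 1, 22 without 0.1 µM replicate 4, 15 without the 3 doubted libraries and 10 with DESeq2. The highest median with a library left out was -0.113, which argues against any single library as the source of the median. Gene counts at 0.1 µM ran from 12794900 to 15331102 (15.33 M), overlapping the DMSO range of 13790767 to 15420019. This argues against depth, although 2 libraries lay below that range. With the share of reads outside genes as a covariate the median was -0.062, between the values expected with and without that cause. The share was higher in all 4 libraries at 0.1 µM, so a difference in unspliced or intergenic RNA may be the source and cannot be told apart from the dose.

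Cell cycle genes were lower and photoreceptor genes higher at 10 µM. With a library left out the cell cycle median stayed at or below -0.461 and the photoreceptor median at or above 0.171. This argues against any single library as the source of the medians, and does not test several libraries together. Of the cell cycle genes 21 fell, but 13 did without DMSO replicate 2, 10 without 10 µM replicate 1 and 12 without 10 µM replicate 2. The test for cell types assumed that a smaller share of dividing cells raises the lists of all differentiated tissues alike. Of 14 tissue lists 8 had a median above 0 and 6 below. Past the threshold of fry 3 rose (neurons 0.107, glia 0.113, neuroendocrine 0.35) and 2 fell (epidermis -0.288, cartilage -0.275). The rule was written after the list results were seen, so no conclusion on shares of cell types is drawn from it. These values show only that the tissue lists did not all rise alike. They do not test a loss of dividing cells that differs between tissues. More neural or less skin and skeletal tissue, other mixtures of cell types, and a difference in the pace of development, were not tested and stay open. Another hour of collection, left open above for the clock genes, was not tested for these or the other lists either.

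Chance groupings of the libraries were counted for each comparison by fits of the 8 libraries alone. The real split gave 487 genes at 0.1 µM against at most 6 in any other of the 35 splits, 3000 at 1 µM against 1, and 5146 at 10 µM against 3. Only 1 of 35 splits, the real one, reached each count, which argues against chance but cannot exclude it. The real split alone also reached the count for 10 against 0.1 µM (3522, highest other split 0) and for 10 against 1 µM (1304, highest other split 3). For the slope the real assignment gave 3851 genes and the highest of the other 99 assignments 8, out of 100. Other splits mix libraries of both groups, so a real difference widens the spread within their groups and lowers their counts. Splits also cannot tell the dose from any other difference between the groups. For 1 against 0.1 µM the splits do not argue against chance: the real split gave 7 genes and the highest other split 19, with 2 splits reaching 7. The counts of lists called with the preset correlation were 17, 16 and 22, and the highest other splits gave 25, 19 and 27. Of 35 splits 13, 10 and 3 were as large, so the splits do not argue against chance for the number of lists at any dose.

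In 30 of 484 groups of 4 libraries (118 named genes in each of 4 groups, and 12 groups of library measures), the farthest library stood apart from the other 3 by more than 0.829 of the group's range; chance gives about 1 in 20, or 24.2 groups. In DMSO the ratio was 0.869 for dbpb, 0.851 for foxo3b and 0.882 for COL2A1 ENSDARG00000011407 (replicate 1), 0.878 for IDI1 and 0.906 for ldlra (replicate 2), 0.91 for FOXO1 ENSDARG00000099555 and 0.883 for krt4 (replicate 3), and 0.882 for HSD11B2, 0.882 for cyp2aa9, 0.929 for CYP24A1 and 0.841 for bub1bb (replicate 4). At 0.1 µM it was 0.864 for ldlra (replicate 1), 0.878 for PCK1 and 0.891 for GAD2 (replicate 2), and 0.837 for tsc22d3 (replicate 4). At 1 µM it was 0.863 for ldlrb and 0.853 for EPAS1 ENSDARG00000008697 (replicate 1), 0.83 for guca1c and 0.829 for ESR2 ENSDARG00000034181 (replicate 2), 0.838 for cyp2aa9 and 0.867 for eno2 (replicate 3), and 0.834 for nfkbiab and 0.86 for anxa1b (replicate 4). At 10 µM it was 0.952 for EGLN2, 0.883 for SOX9 ENSDARG00000043923 and 0.885 for IRS2 ENSDARG00000037099 (replicate 2), 0.85 for insig1 (replicate 3), and 0.842 for cyp2k6, 0.873 for icn and 0.845 for krt4 (replicate 4).

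Entries that name no gene also differed. Reads outside annotated genes made up 37.0% of unique reads at 0.1 µM, above every DMSO library, and reads not uniquely aligned made up 38.47 ± 2.14% of all entries at 10 µM against 29.2 ± 2.99% in DMSO (SD, n = 4; exact permutation p = 0.0286 each, 2-sided, adjusted to 0.0858 over 6 tests).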

How the results depend on the processing

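The covariate and the fit without 3 doubted libraries were chosen after seeing the data; all other alternatives were planned. Counts of changed genes at 0.1, 1 and 10 µM, between doses and with dose rank stayed within 1.5 times their value with DESeq2's size factors and with either filter. DESeq2 and the exact test of edgeR moved the 1 against 0.1 µM count alone, from 208 to 586 and 506. In fits of 2 groups the 0.1 µM count was 487 and the 1 against 0.1 µM count 7, with fewer libraries to estimate the spread. Without the 3 doubted libraries these counts were 1165 and 401. With the covariate the counts were 207 at 0.1 µM, 1076 at 1 µM, 275 for 10 against 0.1 µM and 53 for 10 against 1 µM; the share differs between these groups, and the cause was not tested further. With each library left out the counts ranged from 411 to 1117 at 0.1 µM, 2580 to 4394 at 10 µM, 32 to 630 for 1 against 0.1 µM, 2961 to 5114 for 10 against 0.1 µM and 528 to 1637 for 10 against 1 µM. At 0.1 µM DMSO replicates 3 (411) and 4 (455) and 0.1 µM replicate 4 (1117) moved the count by over 1.5 times, and at 10 µM replicate 2 (2580) did. Those of the other comparisons are DMSO replicate 1 (131), 0.1 µM replicates 1 to 4 (377, 32, 32, 630), 1 µM replicates 1 to 4 (40, 431, 36, 51) and 10 µM replicate 1 (133) for 1 against 0.1 µM; 10 µM replicate 2 (2961) for 10 against 0.1 µM; and 1 µM replicates 2 (528) and 4 (843) and 10 µM replicates 1 (628), 2 (543) and 4 (830) for 10 against 1 µM. With the replicate block the counts were 689, 2613, 3819, 222, 4373, 1227 and 3516, within 1.5 times of the main values, but RPS2 and RPL10A lost their calls at 0.1 µM (adjusted p = 0.064 and 0.0808), so that 0 ribosomal genes passed in edgeR and 58 had an unadjusted p under 0.05; residual correlations of equal replicate numbers across groups ran from -0.178 to 0.229 over 24 pairs (median -0.0015). List counts were 3 at each dose with an estimated correlation and 6 at 0.1 µM with fry. The lens list at 0.1 µM turned upward with the covariate (adjusted p = 6.62e-06; the cause was not tested). With split controls the correlations of fold changes were 0.369, 0.141 and 0.449 and the covariances 0.0286, 0.0122 and 0.0467, and the genes higher at both doses fell from 416, 273 and 899 to means of 151.5, 113.3 and 416 and those lower at both from 177, 91 and 570 to 39, 15.5 and 153.7; splitting ends the sharing and also leaves fewer controls per dose, and the parts were not separated. Of 230 results on named genes 212 were called; 168 of these kept the call in every alternative, 15 lost it with some library left out and 42 in another setting, 35 of them with the covariate. DESeq2 lost none of the 225 it could test.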

Other observations

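Every test in this part was planned. Neuroendocrine genes were higher at 10 µM. CRH, the hypothalamic releasing hormone of the stress axis, rose by 0.74 ± 0.13 log2 units (SE, n = 4 per group, adjusted p = 0.000292 by edgeR), TRH by 0.52 ± 0.11, VIP by 0.49 ± 0.11 and adcyap1b by 0.40 ± 0.05, and 5 of 20 neuroendocrine genes rose in all (8 adjusted over the list alone; list adjusted p = 0.000928, adjusted p = 0.12 with an estimated correlation). Among heat shock genes HSF2 rose by 0.83 ± 0.09 and HSP90AA1 ENSDARG00000024746 by 0.99 ± 0.11, while SERPINH1 ENSDARG00000019949, a collagen chaperone, fell by 0.94 ± 0.20. Of 28 heat shock genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0864). The stress-induced gene TP53INP1 rose by 1.05 ± 0.10. The intelectin gene itln3 rose by 2.31 ± 0.46 (adjusted p = 0.00126) from a mean of 0.249 CPM.

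Genes of DNA methylation went both ways at 10 µM. Of 23 tested genes 6 fell and 2 rose (9 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.109). The methyltransferase genes dnmt3bb.3, DNMT3B and dnmt3ba fell by 0.60 ± 0.12, 0.39 ± 0.08 and 0.39 ± 0.09. MAT2A ENSDARG00000040334, which makes the methyl donor, rose by 0.39 ± 0.07. The number falling was 3 without DMSO replicate 2, without DMSO replicate 4, without 10 µM replicate 1 or without 10 µM replicate 2. ESR2 ENSDARG00000034181, an estrogen receptor gene, rose at 1 µM from 3.57 ± 0.278 to 10.1 ± 1.85 CPM (adjusted p = 8.71e-07).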
